A study of Mus musculus with 9 samples.

How the data were processed

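Expression was measured in 9 libraries, 3 from each of 3 gates of sorted dermal cells of newborn mice (CD49f-neg, CD49f-low and CD49f-high). Per the labels' protocols, sorted cells were lysed at once in Trizol, total RNA was taken, and libraries were made with the NEBNext Ultra kit. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript and mapped fragments), with 1 column per library and 84809 rows. Per the submitters' processing notes, FastQC, TopHat2 and StringTie were used on the genome build GRCm38, with no versions, order or filters given. Per the file headers, each row carries a row identifier, the symbols of the annotated genes it covers and their coordinates. Of the rows, 24946 had a symbol and 1002 had 2 or more, and a row that covers several genes is reported as uncertain as to which gene it measured. The labels do not state the strand, so genes that overlap on opposite strands are uncertain too.

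Libraries were grouped by the gate in their titles. The depth was estimated from the FPKM of single-exon genes of GENCODE M21, whose lowest values pile up at whole numbers of fragments. This gave about 23687701 to 27273580 fragments per library. The FPKM of a library summed to 423745 to 543842, and its 10 most abundant rows, among them small nuclear and signal recognition particle RNAs, held 47.5% to 61.3% of that sum. FPKM were used as deposited, as log2(FPKM + 1), with rows of at least 1 FPKM in at least 3 libraries. This left 20523 rows, of which 12852 had a symbol, 7671 had none and 861 had 2 or more.

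Groups were compared with limma 3.58.1 in R 4.3.3 (group means model, empirical Bayes with a mean-variance trend, 6 residual degrees of freedom), with a moderated F test over the 3 gates and 3 contrasts. The p-values were adjusted by the Benjamini-Hochberg method over all rows tested, and a gene was called at an adjusted p under 0.05. The p-values measure the spread between these samples, since the labels do not say whether replicates came from separate animals. Of 39 gene lists of cell types, pathways and cell functions, the 34 with at least 5 members measured were tested with limma's camera (preset correlation 0.01) and adjusted over the lists. For each list the member calls were also adjusted over the list alone. The lists, the comparisons, the tests and the alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time. They were Itga6, Itgb1 and Itgb4, and, per contrast, the 8 called genes with the highest and the 8 with the lowest fold change among those with no overlap between the groups and a mean of at least 10 FPKM in the higher group, leaving out predicted and mitochondrially encoded genes. Per list, up to 4 called members with the smallest adjusted p were added, or 2 abundant members where none was called, of which the text names a part. The result of 1 gene named by the rule is not reported here. A gene was counted as graded when it was called in the same direction from negative to low and from low to high.

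Alternatives were a pseudocount of 0.1, no filter, a stricter filter (at least 5 FPKM in at least 3 libraries), median-of-ratios scaling, quantile normalization, no trend, the replicate number as a block, each library left out in turn, a fit on the 6 libraries compared, a fold of at least 2, and, for lists, camera with an estimated correlation and fry. Whether the replicate numbers pair the samples was checked from deviations from the group means. Libraries of the same number correlated at 0.252 to 0.520 and libraries of different numbers at -0.453 to 0.118. In 18 of 18 comparisons a library correlated best with its own number, so the values pair the numbers, while the labels give no source for them. The main tests did not use this pairing, which entered only as the block among the alternatives and in the counts over other splits. The method was tested on simulated data with 200 changed rows of 20523. The changed rows were drawn from those with a mean log2(FPKM + 1) above 2, so the recovery does not cover rows near the filter. The noise was independent between libraries, with no pairing of the replicate numbers and no shift of all rows, unlike the data. In that setting the method recovered 84%, 89% and 83% of 2-fold changes and 98%, 97% and 96% of 4-fold changes in the 3 contrasts. Of its calls, 6.67%, 2.62% and 3.76% were false. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Sequence reads were not used here.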

Results

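Gene expression was measured by RNA sequencing of 9 libraries from dermal mesenchymal cells of newborn mice that carried a Krt14-driven Cre recombinase and the Rosa26-mTmG reporter, a membrane fluorescent protein that changes colour in cells with a history of Cre. Cells had been sorted by flow cytometry on CD49f, the integrin α6 subunit, into a negative, a low and a high gate, with 3 libraries per gate (CD49f-neg, CD49f-low and CD49f-high, replicates 1 to 3). The deposited unit was FPKM per gene. The spacing of the low FPKM values put 1 FPKM over 1 kilobase of transcript at 23.7 to 27.3 fragments, an estimate of depth, and the depth relative to CD49f-neg replicate 1 ranged from 0.941 to 1.08. Of 84809 gene rows, 20523 reached the filter and were tested, 12852 of them with a gene symbol. All levels below are FPKM as mean ± SD with n = 3 per gate, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The first principal component took 45.4% of the variance, the second 23.7% and the third 12.0%. On the third, replicate 1 of every gate (20.79 to 32.96) lay apart from all replicates 2 and 3 (-18.66 to -10.20).

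The gates were first compared for the transcripts of the sorted antigen and its partners. Itga6, which encodes CD49f (row identifier MERGE.25277, GRCm38 chromosome 2, 71745616 to 71858416), stood at 0.475 ± 0.216 FPKM in CD49f-neg, 5.51 ± 0.979 in CD49f-low and 19.9 ± 4.11 in CD49f-high. It rose from the negative to the low gate by 2.14 (SE 0.18, adjusted p = 7.36e-05) log2 units and from the low to the high gate by 1.67 (SE 0.18, adjusted p = 0.000282), in limma's test. Over the whole range, from negative to high, the change was 3.81 (SE 0.18, adjusted p = 3.09e-06). The laminin receptor partner Itgb4 (chromosome 11, 115974709 to 116008412), the hemidesmosomal β subunit, stood at 0.0823 ± 0.0198, 0.682 ± 0.0357 and 8.38 ± 4.87 FPKM, and rose from low to high by 2.29 log2 units (limma adjusted p = 0.00303). Its 3 CD49f-high libraries were unequal, at 2.78, 10.7 and 11.6 FPKM. Its low-to-negative difference of 0.64 did not pass the test (adjusted p = 0.270), but passed with a pseudocount of 0.1 (adjusted p = 0.0176) and without CD49f-high replicate 1 (adjusted p = 0.00437). Itgb1 (chromosome 8, 128685654 to 128733200), the common β1 subunit, was abundant in all 3 gates, at 104 ± 3.27, 121 ± 9.33 and 165 ± 27.2 FPKM. It was higher in CD49f-high than in CD49f-neg by 0.64 log2 units (adjusted p = 0.00815). Between the high and low gates Itgb1 missed the threshold (adjusted p = 0.0591), and passed it with the replicate block (adjusted p = 0.0262), after median-of-ratios scaling (0.0119), after quantile normalization (0.00499) and without CD49f-high replicate 2 (0.0304). Between the low and negative gates its difference of 0.20 did not pass the test (adjusted p = 0.321) and turned to -0.08 after median-of-ratios scaling.

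**Figure D1:**
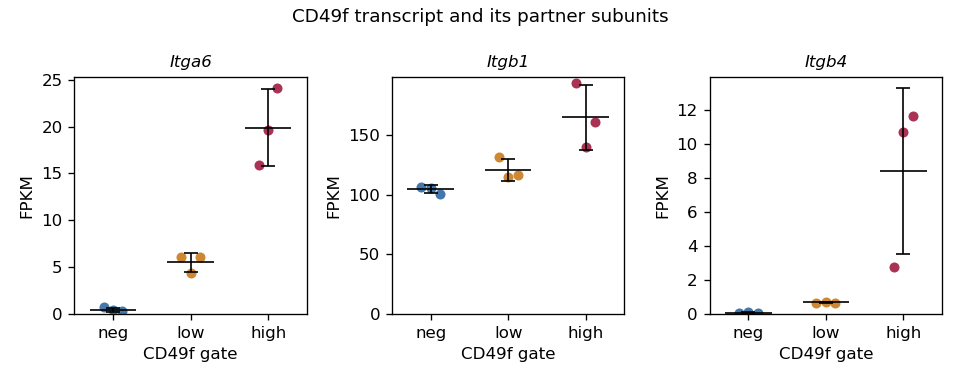
FPKM of Itga6, Itgb1 and Itgb4 (y axis, linear from 0) in each library of the 3 CD49f gates (x axis). Points are libraries, long bars are means and capped bars are 1 SD (n = 3). Itga6 averaged 0.475, 5.51 and 19.9 FPKM from the negative to the high gate.

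The comparison of CD49f-low with CD49f-neg asked how dermal cells with a low CD49f signal differed from those with none. Pigment cell genes showed the highest fold changes. Pmel, the fibril protein of melanosomes (chromosome 10, 128706258 to 128720238), stood at 199 ± 19.8 against 0.320 ± 0.0217 FPKM, and Dct, a melanin synthesis enzyme, at 169.6 ± 27.9 against 0.171 ± 0.0524. Genes of the dermal papilla, the mesenchymal signalling centre of the hair follicle, rose as well, among them the serine protease Corin (17.6 ± 4.49 against 0.373 ± 0.0665 FPKM). Genes of the fibroblast matrix fell, among them Lox, the enzyme that cross-links collagen and elastin (64.6 ± 8.94 against 202 ± 26.3 FPKM).

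In the melanocyte list, 12 of 12 measured members rose (12 adjusted over the list alone), with a median 3.58 log2 units above that of all rows (camera direction up, adjusted p = 1.08e-20, and adjusted p = 0.0313 with an estimated correlation). The pigment genes Mlana and Tyrp1 rose by 5.26 (SE 0.15, adjusted p = 3.43e-07) and 4.68 (SE 0.14, adjusted p = 3.43e-07) log2 units. Kit, the receptor tyrosine kinase of melanoblasts, rose from 0.445 ± 0.121 to 23.1 ± 4.86 FPKM, and Sox10, a transcription factor of melanocytes and glia, from 0.0821 ± 0.0222 to 23.1 ± 3.15. Ptgds, a prostaglandin D synthase, Mcoln3, a cation channel of endosomes and lysosomes, and Cdh1, the adhesion molecule E-cadherin, stood at 43.5 ± 3.10 against 0.0562 ± 0.0383, 18.9 ± 3.89 against 0.0435 ± 0.0206 and 18.7 ± 2.71 against 0.0794 ± 0.0569 FPKM. In the neural crest and skin-derived precursor list, 10 of 18 measured members rose and 1 fell (12 and 1 adjusted over the list alone), with camera direction up, adjusted p = 0.000667, and adjusted p = 0.272 with an estimated correlation. The neural crest regulators Pax3 and Tfap2a rose by 3.09 and 3.16 log2 units. In the Schwann cell list 6 of 21 measured members rose (7 adjusted over the list alone, with 1 lower), and the list was not called (camera adjusted p = 0.525), but it was with no filter (adjusted p = 0.0370), after median-of-ratios scaling (0.0303), after quantile normalization (0.0279), in a fit on the 6 libraries compared (0.0242) and without CD49f-high replicate 1 (0.0248).

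In the dermal papilla and condensate list, 14 of 19 measured members rose (15 adjusted over the list alone), with a median 1.18 log2 units above that of all rows (camera direction up, adjusted p = 4.21e-09, and adjusted p = 0.145 with an estimated correlation). The Wnt deacylase Notum rose by 2.82 (SE 0.16, adjusted p = 1.32e-05) log2 units, alkaline phosphatase Alpl by 3.03 (SE 0.23, adjusted p = 3.95e-05) and the transcription factor Sox2 by 2.87 (SE 0.23, adjusted p = 5.02e-05). In the Notch pathway list, 8 of 14 measured members rose (12 adjusted over the list alone, with 1 lower), with camera direction up, adjusted p = 8.45e-05, and adjusted p = 0.0778 with an estimated correlation. The Notch ligand Dll1 went from 0.527 ± 0.127 to 12.4 ± 1.72 FPKM, and the target genes Hey1 and Hey2 rose by 1.78 and 2.11 log2 units. The growth factors Bmp7 and Inhba rose by 2.77 and 3.10 log2 units. In the papillary dermis list 8 of 16 measured members rose and 2 fell (9 and 3 adjusted over the list alone), with Prdm1, a transcription factor of papillary fibroblasts, up by 2.64 and the surface peptidase Dpp4 changed by -1.71. That list was not called (camera adjusted p = 0.525), but it was with no filter (adjusted p = 0.0375), after quantile normalization (0.0252) and, in direction up, by fry (0.0144).

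In the fibroblast list, 13 of 19 measured members fell (13 adjusted over the list alone), with camera direction down, adjusted p = 4.66e-19, and adjusted p = 0.0655 with an estimated correlation. The collagen gene Col1a2 went from 2182 ± 292 to 829 ± 94.6 FPKM, and decorin, Dcn, from 297 ± 41.7 to 116 ± 17.6. In the fibrillar collagen and elastic fibre list 1 of 27 measured members rose and 12 fell (2 and 14 adjusted over the list alone), with camera direction down, adjusted p = 1.33e-13, and adjusted p = 0.0778 with an estimated correlation, and both lists share members such as Loxl1. The elastic fibre protein Mfap4 changed by -1.65 (SE 0.22, adjusted p = 0.00124) log2 units. Steep falls were those of the secreted proteins C1qtnf3 (-2.78 log2 units), Sfrp2, a Wnt-binding protein (-2.36), the carboxypeptidases Cpe (-2.45) and Cpz (-1.83), Smoc2, a calcium-binding matrix protein (-2.21), Ltbp2, which binds elastic microfibrils (-2.05), and Egfl6 (-1.83). A row that joins Pcsk6 and Snrpa1 also fell (-1.86), and which gene it measured is uncertain. In the protease and inhibitor list 4 of 20 measured members fell (5 adjusted over the list alone, with 1 higher), with camera direction down, adjusted p = 7.08e-05, and adjusted p = 0.0778 with an estimated correlation. The collagen propeptidase Adamts2 changed by -1.22 log2 units. In the reticular and hypodermal list 2 of 15 measured members rose and 3 fell (2 and 4 adjusted over the list alone), with the imprinted gene Peg3 at -0.93 (camera direction down, adjusted p = 5.16e-05, and adjusted p = 0.208 with an estimated correlation). Fry, which tests a list against no change and not against other genes, did not call the reticular list (adjusted p = 0.138). Of its members, 5 were called lower after median-of-ratios scaling and 4 after quantile normalization, and both higher calls ended after either.

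Marker lists of other cell types also moved. In the skeletal muscle and satellite cell list 7 of 8 measured members rose (7 adjusted over the list alone), including Cdh15, a cadherin of myogenic cells, at 2.99 ± 1.15 against 0.103 ± 0.0314 FPKM (camera direction up, adjusted p = 1.57e-05, and adjusted p = 0.141 with an estimated correlation). The myogenic factor Myod1 averaged 2.49 FPKM in CD49f-low and was listed at 0 in all 3 CD49f-neg libraries. In the chondrocyte and osteoblast list 6 of 6 measured members rose (6 adjusted over the list alone), with the cartilage proteoglycan Acan at 7.52 ± 3.73 against 0.222 ± 0.108 FPKM (camera direction up, adjusted p = 5.16e-05, and adjusted p = 0.0778 with an estimated correlation). Only 8 of 19 skeletal muscle and 6 of 12 chondrocyte and osteoblast members were measured. The filter can be met by the 3 libraries of 1 gate, so members low in every gate dropped out. In the keratinocyte list 8 of 16 measured members rose (13 adjusted over the list alone), with camera direction up, adjusted p = 5.16e-05, and adjusted p = 0.334 with an estimated correlation. Of its members, 6 were called higher after median-of-ratios scaling and 4 after quantile normalization. Its member Cdh3, P-cadherin, stood at 10.3 ± 2.46 against 0.227 ± 0.194 FPKM. In the proliferation list 19 of 32 measured members rose (32 adjusted over the list alone), with Mcm7, a subunit of the replicative helicase, up by 0.69 (camera direction up, adjusted p = 4.30e-07, and adjusted p = 0.411 with an estimated correlation). Of its members, 4 were called higher after median-of-ratios scaling and 7 after quantile normalization. In the pericyte list 6 of 15 measured members rose and 2 fell (6 and 2 adjusted over the list alone) and in the integrin list 4 of 15 measured members rose and 1 fell (4 and 2 adjusted over the list alone), and neither was called (camera adjusted p = 0.819 and 0.779), but fry called both, in direction up (adjusted p = 0.0493 and 0.00116). Immune, mast, erythroid, neuronal and pluripotency genes were too rarely above the filter for a list test, with 1 of 18, 4 of 9, 3 of 7, 3 of 10 and 3 of 12 members measured.

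Of 20523 rows, limma called 3160 at an adjusted p under 0.05, 2623 higher and 537 lower in CD49f-low, and 6737 had an unadjusted p under 0.05. The replicate block raised the count to 5806. The median log2 fold change of all rows was 0.21, so changes of single genes are read against that shift. After median-of-ratios scaling the calls were 1117 higher and 1093 lower, and after quantile normalization 1040 higher and 1004 lower. Leaving out CD49f-neg replicate 3 gave 1614 calls, CD49f-low replicate 2 gave 1726 and CD49f-low replicate 3 gave 1681. Camera called 17 of 34 lists, 12 up and 5 down, and 1 held its call with an estimated correlation, the melanocyte list.

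Some of the called lists lost the call in other settings than the estimated correlation. The basement membrane list (11 of 19 measured members rose, 11 adjusted over the list alone, with 1 lower, direction up, adjusted p = 0.0176, or adjusted p = 0.413 with an estimated correlation) lost it with the replicate block (adjusted p = 0.0540) and without CD49f-neg replicate 1 (0.0644). Of its members, 9 were called higher after median-of-ratios scaling and 7 after quantile normalization. Its laminin and collagen members Lamc3 and Col15a1 rose by 2.36 and 1.99 log2 units, and both calls of these genes held in every setting tried. The smooth muscle list (6 of 15 measured members rose, 9 adjusted over the list alone, direction up, adjusted p = 0.0259, or adjusted p = 0.671 with an estimated correlation) lost it with the stricter filter (adjusted p = 0.0534), with the replicate block (0.131), without CD49f-neg replicate 1 (0.0867) and without CD49f-low replicate 3 (0.0519). Its members Acta2 and Myh11 rose by 4.02 and 3.25. The glycolysis list (7 of 21 measured members rose, 7 adjusted over the list alone, direction up, adjusted p = 0.0491, or adjusted p = 0.754 with an estimated correlation) lost it with the stricter filter (adjusted p = 0.0768), with no trend (0.0544), with the replicate block (0.123), without CD49f-neg replicate 1 (0.0537), without CD49f-neg replicate 3 (0.107), without CD49f-low replicate 1 (0.0724) and without CD49f-low replicate 2 (0.106). Of its members, 3 were called higher after median-of-ratios scaling and 2 after quantile normalization. Its member Vegfa, an angiogenic growth factor, rose by 0.92. The cholesterol synthesis list (5 of 22 measured members rose, 8 adjusted over the list alone, direction up, adjusted p = 0.0376, or adjusted p = 0.671 with an estimated correlation) lost it with the stricter filter (adjusted p = 0.0534), without CD49f-neg replicate 1 (0.183), without CD49f-low replicate 2 (0.139) and without CD49f-low replicate 3 (0.123). Of its members, 2 were called higher after quantile normalization, and all 5 calls ended after median-of-ratios scaling. In the Hedgehog list (1 of 12 measured members rose and 1 fell, 1 and 3 adjusted over the list alone, direction down, adjusted p = 0.0491, or adjusted p = 0.671 with an estimated correlation) the median was 0.07 and the test direction down, since the median of all rows lay higher. It lost its call with a pseudocount of 0.1 (adjusted p = 0.0503), with no filter (0.269), with the stricter filter (0.0620), after quantile normalization (0.176), with no trend (0.0516), with the replicate block (0.1001), in a fit on the 6 libraries compared (0.0624), without CD49f-neg replicate 3 (0.220), without CD49f-low replicate 1 (0.0865), without CD49f-low replicate 2 (0.106), without CD49f-high replicate 1 (0.0588) and without CD49f-high replicate 2 (0.0511), and fry did not call it (0.789). After either scaling 3 of its members were called lower.

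The comparison of CD49f-high with CD49f-neg spanned the full range of the sort. Genes of mural cells, the contractile cells around blood vessels, rose. Rgs5, a GTPase-activating protein of pericytes (chromosome 1, 169655501 to 169695813), stood at 356 ± 98.0 against 0.249 ± 0.166 FPKM, Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194527 to 14291408), at 191 ± 76.5 against 0.354 ± 0.0797, and Acta2, smooth muscle actin, at 167 ± 77.2 against 1.27 ± 0.252. Schwann cell genes rose too, such as Erbb3, the glial neuregulin receptor (21.1 ± 11.8 against 0.115 ± 0.0665 FPKM). Fibroblast matrix genes fell, such as elastin, Eln, and Lox (Lox at 33.5 ± 5.62 against 202 ± 26.3 FPKM).

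In the pericyte list, 14 of 15 measured members rose and 1 fell (14 and 1 adjusted over the list alone), with a median 2.68 log2 units above that of all rows (camera direction up, adjusted p = 3.68e-11, and adjusted p = 0.164 with an estimated correlation). CD49f-high replicate 2 was the lowest CD49f-high library in 13 of the 15, with a median of -0.67 against the others. The adhesion molecule Mcam, the vessel-wall connexin gene Gja4 and vitronectin, Vtn, rose by 3.97 (SE 0.14, adjusted p = 1.34e-06), 4.17 (SE 0.22, adjusted p = 4.66e-06) and 3.85 (SE 0.19, adjusted p = 3.28e-06) log2 units. In the smooth muscle list 13 of 15 measured members rose and 1 fell (13 and 2 adjusted over the list alone), with camera direction up, adjusted p = 3.91e-07, and adjusted p = 0.180 with an estimated correlation. Desmin, Des, the muscle intermediate filament protein, rose from 1.67 ± 0.552 to 42.5 ± 13.2 FPKM. Notch3, the mural cell Notch receptor, and Nrarp, a Notch target, rose by 5.07 (SE 0.29, adjusted p = 5.00e-06) and 5.09 (SE 0.38, adjusted p = 1.89e-05). Gucy1a3, a subunit of the nitric oxide receptor, Epas1, a hypoxia-inducible transcription factor, and Olfml2a rose by 5.07, 4.85 and 5.07 log2 units. In the Notch pathway list 9 of 14 measured members rose and 1 fell (10 and 1 adjusted over the list alone), with camera direction up, adjusted p = 0.000506, and adjusted p = 0.163 with an estimated correlation. In the basement membrane list 13 of 19 measured members rose and 2 fell (13 and 2 adjusted over the list alone), with camera direction up, adjusted p = 1.01e-06, and adjusted p = 0.163 with an estimated correlation. Its collagens Col4a1 and Col18a1 stood at 701 ± 102 against 97.7 ± 2.75 and 149 ± 46.2 against 5.36 ± 0.821 FPKM. In the integrin list 9 of 15 measured members rose and 3 fell (9 and 3 adjusted over the list alone), with camera direction up, adjusted p = 0.0105, and adjusted p = 0.163 with an estimated correlation. The call was lost with the stricter filter (adjusted p = 0.0545). Itga7, the laminin-binding α7 subunit, rose from 0.464 ± 0.154 to 39.8 ± 10.1 FPKM.

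In the Schwann cell list, 17 of 21 measured members rose and 1 fell (18 and 1 adjusted over the list alone), with camera direction up, adjusted p = 4.56e-08, and adjusted p = 0.256 with an estimated correlation. Its median lay 2.70 log2 units above that of all rows. The glial transcription factors Foxd3 and Sox10 went from 0.0430 ± 0.0321 and 0.0821 ± 0.0222 to 25.8 ± 16.2 and 28.3 ± 19.1 FPKM, and the fatty acid-binding protein Fabp7 from 0.0106 ± 0.0184 to 6.73 ± 3.24. CD49f-high replicate 1 stood apart in this list, with a median of -1.76 log2 units against the other CD49f-high libraries. Without any one library in turn the Schwann list kept its call (highest camera adjusted p = 1.18e-06). CD49f-high replicate 1 had a median of 1.76 in the adipocyte list, with the adipokine Adipoq at 132 FPKM against 2.30 and 1.16. In the adipocyte list 3 of 12 measured members rose (5 adjusted over the list alone), with camera direction up, adjusted p = 0.00352, and adjusted p = 0.382 with an estimated correlation. The call was lost with the stricter filter (adjusted p = 0.170). Its member Ebf2, a transcription factor of adipose precursors, rose from 0.109 ± 0.0429 to 5.29 ± 1.13 FPKM. The mitochondrially encoded list (3 of 16 measured members rose, 3 adjusted over the list alone, direction up, adjusted p = 0.00784, or adjusted p = 0.465 with an estimated correlation) lost its call with the stricter filter (adjusted p = 0.143), with fry (0.0706) and without CD49f-high replicate 1 (0.0678). The nuclear oxidative phosphorylation list (11 of 78 measured members rose and 1 fell, 5 and 1 adjusted over the list alone, direction up, adjusted p = 0.0137, or adjusted p = 0.674 with an estimated correlation) lost it with fry (adjusted p = 0.174), without CD49f-neg replicate 1 (0.160) and without CD49f-high replicate 1 (0.471). Cox4i2, a cytochrome oxidase subunit that also stands in the pericyte list, rose by 3.69 log2 units. The median of the nuclear list was 0.24, and 66 of its 78 measured members were not called.

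In the keratinocyte list, 15 of 16 measured members rose (16 adjusted over the list alone), with camera direction up, adjusted p = 7.31e-11, and adjusted p = 0.163 with an estimated correlation. CD49f-high replicate 3 was the lowest CD49f-high library in 13 of the 16, with a median of -0.75 against the others. Col17a1 and Lama3, which anchor basal keratinocytes, were at 3.70 ± 1.27 against 0.133 ± 0.0222 and 2.93 ± 0.575 against 0.0412 ± 0.00125 FPKM. The rows that hold Krt5 and Krt14 each join several keratin genes, and are uncertain as to which keratin they measured. In the blood endothelial list 6 of 12 measured members rose and 1 fell (7 and 1 adjusted over the list alone), with camera direction up, adjusted p = 0.00612, and adjusted p = 0.180 with an estimated correlation. Cdh5, the endothelial cadherin, was at 5.30 ± 1.96 against 0.0785 ± 0.0988 FPKM. Only 12 of the 22 members of the blood endothelial list were measured. In the lymphatic list 7 of 10 measured members rose and 3 fell (7 and 3 adjusted over the list alone), with camera direction up, adjusted p = 0.0232, and adjusted p = 0.321 with an estimated correlation. The call was lost with the stricter filter (adjusted p = 0.553) and with the replicate block (0.0740). The lymphatic genes Reln and Lyve1 rose by 3.26 and 2.87 log2 units. In the melanocyte list 7 of 12 measured members rose (7 adjusted over the list alone), with camera direction up, adjusted p = 0.000697, and adjusted p = 0.180 with an estimated correlation. In the neural crest list 12 of 18 measured members rose and 2 fell (12 and 2 adjusted over the list alone), with camera direction up, adjusted p = 0.000697, and adjusted p = 0.180 with an estimated correlation. In the chondrocyte and osteoblast list 4 of 6 measured members rose (4 adjusted over the list alone), with camera direction up, adjusted p = 0.00671, and adjusted p = 0.180 with an estimated correlation. In the skeletal muscle list 4 of 8 measured members rose (4 adjusted over the list alone), with camera direction up, adjusted p = 0.0297, and adjusted p = 0.342 with an estimated correlation. The call was lost without CD49f-neg replicate 2 (adjusted p = 0.0506). Of its members, 4 were called higher after median-of-ratios scaling and 2 after quantile normalization.

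Chemokine, cytokine and complement genes rose as a group: 14 of 21 measured members rose (16 adjusted over the list alone), with camera direction up, adjusted p = 5.02e-06, and adjusted p = 0.180 with an estimated correlation. The eotaxin gene Ccl11 and the cytokine Il6 rose by 3.75 (SE 0.30, adjusted p = 2.45e-05) and 3.13 (SE 0.29, adjusted p = 6.32e-05) log2 units. Among genes known to respond to tissue dissociation, 8 of 22 measured members rose (9 adjusted over the list alone), with camera direction up, adjusted p = 0.00138, and adjusted p = 0.454 with an estimated correlation. The cytokine signalling inhibitor Socs3 and the mRNA decay factor Zfp36 rose by 2.55 and 2.06 log2 units. In the interferon list 7 of 14 measured members rose and 1 fell (7 and 1 adjusted over the list alone), with camera direction up, adjusted p = 0.0105, and adjusted p = 0.253 with an estimated correlation. In the glycolysis and hypoxia list 12 of 21 measured members rose (12 adjusted over the list alone), with camera direction up, adjusted p = 0.000281, and adjusted p = 0.296 with an estimated correlation. The growth factor Vegfa rose by 1.07 log2 units. In the proliferation list 5 of 32 measured members rose (5 adjusted over the list alone), with camera direction up, adjusted p = 0.00259, and adjusted p = 0.465 with an estimated correlation. The platelet-derived growth factor genes Pdgfa and Pdgfb rose by 2.84 and 2.66.

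In the fibroblast list, 14 of 19 measured members fell (15 adjusted over the list alone, with 1 higher), with camera direction down, adjusted p = 6.46e-11, and adjusted p = 0.163 with an estimated correlation. Lumican, Lum, went from 369.7 ± 27.7 to 85.7 ± 14.0 FPKM, and the transcription factor Twist2 from 12.5 ± 3.50 to 1.45 ± 0.531. In the fibrillar collagen and elastic fibre list 1 of 27 measured members rose and 17 fell (1 and 19 adjusted over the list alone), with camera direction down, adjusted p = 2.15e-10, and adjusted p = 0.163 with an estimated correlation. In the papillary dermis list 2 of 16 measured members rose and 9 fell (2 and 10 adjusted over the list alone), with camera direction down, adjusted p = 7.12e-06, and adjusted p = 0.180 with an estimated correlation. Col7a1, the anchoring fibril collagen, changed by -3.41 (SE 0.19, adjusted p = 4.97e-06) log2 units, and Wif1, a Wnt inhibitor, by -2.68 (SE 0.18, adjusted p = 1.06e-05). In the Wnt list 5 of 30 measured members rose and 14 fell (5 and 15 adjusted over the list alone), with camera direction down, adjusted p = 0.000465, and adjusted p = 0.180 with an estimated correlation. In the Hedgehog list 1 of 12 measured members rose and 9 fell (2 and 10 adjusted over the list alone), with camera direction down, adjusted p = 6.03e-06, and adjusted p = 0.180 with an estimated correlation. The R-spondin receptor Lgr5 and the Hedgehog receptor Ptch1 changed by -2.60 and -1.38 log2 units. The Wnt list shares members such as Wif1 and Lef1 with the papillary list, so their falls are not separate results. Further steep falls were those of C1qtnf3 (-4.57), Sfrp2 (-4.10), Egfl6 (-3.85), Tmem132c (-3.31), the gap junction gene Gja1 (-3.31), Cpz (-3.30) and the opioid precursor Penk (-3.07). In the cytosolic ribosomal protein list 3 of 83 measured members fell (none adjusted over the list alone), with camera direction down, adjusted p = 0.00233, and adjusted p = 0.418 with an estimated correlation. Fry did not call this list (adjusted p = 0.183). Of its members, 11 were called lower after median-of-ratios scaling and 9 after quantile normalization.

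Limma called 4541 rows, 2844 higher and 1697 lower in CD49f-high than in CD49f-neg, and 6972 had an unadjusted p under 0.05. After median-of-ratios scaling the calls were 2480 higher and 2232 lower, and after quantile normalization 2186 higher and 2315 lower. Camera called 27 of 34 lists, 21 up and 6 down, and with an estimated correlation 0 lists reached an adjusted p under 0.05, although 8 had an unadjusted p under 0.05. The dermal papilla list (5 of 19 measured members rose and 6 fell, 6 and 6 adjusted over the list alone) was not called (camera adjusted p = 0.213).

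**Figure D2:**
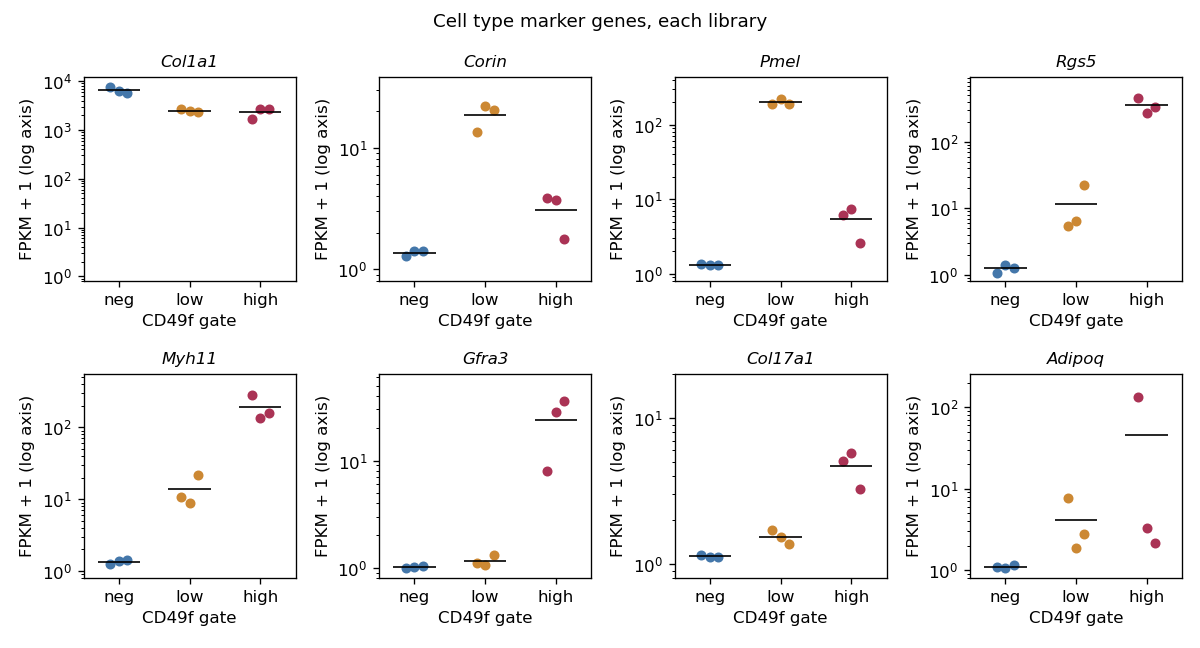
FPKM + 1 (y axis, log scale) of 8 marker genes in each library of the 3 CD49f gates (x axis). Points are libraries in the order of replicates 1 to 3 and bars are means (n = 3). Pmel and Corin were highest in CD49f-low, Rgs5 and Myh11 in CD49f-high, and Gfra3 and Adipoq separated CD49f-high replicate 1 from replicates 2 and 3.

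The comparison of CD49f-high with CD49f-low asked what set apart the cells with the strongest CD49f signal among those that carried it. Pericyte genes were again far higher, with Rgs5 at 356 ± 98.0 against 10.5 ± 9.69 FPKM. Schwann cell genes rose, among them Gfra3, a glial receptor for artemin, at 23.0 ± 14.4 against 0.158 ± 0.133 FPKM. Pigment cell genes fell, with Pmel at 4.39 ± 2.52 against 199 ± 19.8 FPKM. Dermal papilla genes fell as well, such as Crabp1, a retinoic acid-binding protein (4.77 ± 1.61 against 46.8 ± 18.0).

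In the pericyte list, 12 of 15 measured members rose (13 adjusted over the list alone), with a median 2.73 log2 units above that of all rows (camera direction up, adjusted p = 2.57e-20, and adjusted p = 0.104 with an estimated correlation). Abcc9, a subunit of the vascular potassium channel, rose by 3.58 (SE 0.30, adjusted p = 7.20e-05), and the adrenergic receptor Adra2a by 4.21 (SE 0.21, adjusted p = 1.01e-05). In the smooth muscle list 9 of 15 measured members rose and 2 fell (11 and 2 adjusted over the list alone), with camera direction up, adjusted p = 1.77e-07, and adjusted p = 0.171 with an estimated correlation. Myh11 and the actin-binding Lmod1 rose by 3.83 and 1.91 log2 units. In the Schwann cell list 13 of 21 measured members rose and 1 fell (15 and 1 adjusted over the list alone), with camera direction up, adjusted p = 8.39e-12, and adjusted p = 0.171 with an estimated correlation. The potassium channel Kcna1 and the myelin protein Mal rose by 3.46 and 3.24, and Moxd1 and the receptor Gpr17 by 3.90 and 3.63. CD49f-high replicate 1 was the lowest CD49f-high library in 18 of the 19 Schwann members whose mean was higher in CD49f-high than in CD49f-neg, and the list kept its call without any one library (highest camera adjusted p = 3.55e-09). In the adipocyte list, in which that library had the highest median, 1 of 12 measured members rose and 1 fell (1 and 1 adjusted over the list alone), with camera direction up, adjusted p = 0.0299, and adjusted p = 0.563 with an estimated correlation. This call ended with the stricter filter (adjusted p = 0.855, direction down), after median-of-ratios scaling (0.141), after quantile normalization (0.144), with fry (0.331) and without CD49f-high replicate 1 (0.924, direction down). The glycolysis list (1 of 21 measured members rose, 1 adjusted over the list alone, direction up, adjusted p = 0.00405, or adjusted p = 0.468 with an estimated correlation) lost its call with the stricter filter (adjusted p = 0.0637), with fry (0.336) and without CD49f-high replicate 1 (0.136). After either scaling 3 of its members were called higher. The mitochondrially encoded list (limma called 0 of 16 measured members, 0 adjusted over the list alone, with 0 at an unadjusted p under 0.05, direction up, adjusted p = 0.0290, or adjusted p = 0.576 with an estimated correlation) lost it with the stricter filter (adjusted p = 0.325), after median-of-ratios scaling (0.109), after quantile normalization (0.0816), with fry (0.641) and without CD49f-high replicate 1 (0.806, direction down).

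In the dermal papilla and condensate list, 18 of 19 measured members fell (18 adjusted over the list alone), and its median relative to that of all rows was -1.74 (camera direction down, adjusted p = 2.91e-13, and adjusted p = 0.104 with an estimated correlation). Bmp4 and the surface protein Prom1 changed by -2.67 (SE 0.21, adjusted p = 5.70e-05) and -1.46 (SE 0.12, adjusted p = 7.21e-05) log2 units. In the papillary list 14 of 16 measured members fell (14 adjusted over the list alone), with camera direction down, adjusted p = 5.68e-10, and adjusted p = 0.104 with an estimated correlation. The membrane collagen Col23a1 and the Wnt effector Lef1 changed by -2.79 and -2.07. In the melanocyte list 10 of 12 measured members fell (11 adjusted over the list alone), with camera direction down, adjusted p = 1.77e-14, and adjusted p = 0.0828 with an estimated correlation. Dct, Mlana, Tyrp1 and the melanosomal transporter Slc45a2 changed by -5.31, -4.47, -3.49 and -3.26, and Ptgds, Mcoln3 and the melanosomal glycoprotein Gpnmb by -4.51, -3.79 and -3.13. Sox10, which glia also express, stood at 23.1 ± 3.15 and 28.3 ± 19.1 FPKM. In the Wnt list 3 of 30 measured members rose and 20 fell (3 and 21 adjusted over the list alone), with camera direction down, adjusted p = 0.000127, and adjusted p = 0.143 with an estimated correlation. In the Hedgehog list 1 of 12 measured members rose and 8 fell (1 and 10 adjusted over the list alone), with camera direction down, adjusted p = 0.000264, and adjusted p = 0.235 with an estimated correlation. The Wnt inhibitor Dkk1 and the Hedgehog receptor Ptch1 changed by -2.19 and -1.71. The Wnt list shares members with the papillary list, such as Lef1, and with the dermal papilla list, such as Notum. Ptch1 also stands in the dermal papilla list, so the falls of these lists are not separate results. In the skeletal muscle list 4 of 8 measured members fell (5 adjusted over the list alone), with camera direction down, adjusted p = 0.00542, and adjusted p = 0.235 with an estimated correlation.

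In the basement membrane list, 11 of 19 measured members rose and 3 fell (11 and 5 adjusted over the list alone), with camera direction up, adjusted p = 2.70e-07, and adjusted p = 0.104 with an estimated correlation. After either scaling 1 of its members was called lower. In the integrin list 6 of 15 measured members rose and 1 fell (7 and 2 adjusted over the list alone), with camera direction up, adjusted p = 0.000264, and adjusted p = 0.103 with an estimated correlation. Col18a1 and Itga7 rose by 3.34 and 3.10 log2 units. In the chemokine, cytokine and complement list 9 of 21 measured members rose (12 adjusted over the list alone, with 1 lower), with camera direction up, adjusted p = 7.80e-11, and adjusted p = 0.115 with an estimated correlation. Ccl11 and Il6 rose by 2.84 (SE 0.30, adjusted p = 0.000230) and 2.70 (SE 0.29, adjusted p = 0.000258). In the interferon list 4 of 14 measured members rose (5 adjusted over the list alone), with camera direction up, adjusted p = 3.60e-05, and adjusted p = 0.115 with an estimated correlation. Among dissociation stress genes 3 of 22 measured members rose (3 adjusted over the list alone), with camera direction up, adjusted p = 0.000264, and adjusted p = 0.478 with an estimated correlation. This call ended with fry (adjusted p = 0.260). Igfbp5, an IGF-binding protein, rose from 19.6 ± 5.86 to 139 ± 13.1 FPKM.

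In the lymphatic list 7 of 10 measured members rose and 2 fell (7 and 3 adjusted over the list alone), with camera direction up, adjusted p = 6.62e-05, and adjusted p = 0.142 with an estimated correlation. This call ended with the stricter filter (adjusted p = 0.518). In the blood endothelial list 3 of 12 measured members rose and 2 fell (5 and 2 adjusted over the list alone), with camera direction up, adjusted p = 0.00117, and adjusted p = 0.143 with an estimated correlation. After either scaling 5 of its members were called higher. The endothelial adhesion gene Esam rose by 3.04, while the transcription factor Sox18 changed by -2.02. In the keratinocyte list 10 of 16 measured members rose and 2 fell (10 and 2 adjusted over the list alone), with camera direction up, adjusted p = 9.43e-08, and adjusted p = 0.148 with an estimated correlation. This call ended with the stricter filter (adjusted p = 0.434). Its cadherins Cdh1 and Cdh3 changed by -2.16 and -2.14, against the direction of the list. In the reticular list 4 of 15 measured members rose (7 adjusted over the list alone), with camera direction up, adjusted p = 0.000264, and adjusted p = 0.171 with an estimated correlation. Of its members, 7 were called higher after median-of-ratios scaling and 6 after quantile normalization. The matrix protease list (5 of 20 measured members rose and 2 fell, 8 and 5 adjusted over the list alone, direction up, adjusted p = 0.0127, or adjusted p = 0.171 with an estimated correlation) lost its call after quantile normalization (adjusted p = 0.0657) and with fry (0.0537). Of its members, 8 were called higher after median-of-ratios scaling and 8 after quantile normalization. The ribosomal list (6 of 83 measured members fell, none adjusted over the list alone) was called (direction down, adjusted p = 0.00793, or adjusted p = 0.563 with an estimated correlation). Of its members, 2 were called lower after median-of-ratios scaling and 5 after quantile normalization. The proliferation list (3 of 32 measured members fell, none adjusted over the list alone, direction down, adjusted p = 0.0275, or adjusted p = 0.576 with an estimated correlation) lost its call with the stricter filter (adjusted p = 0.0818), with fry (0.0819), without CD49f-low replicate 1 (0.126), without CD49f-low replicate 2 (0.0835) and without CD49f-high replicate 3 (0.119). Of its members, 1 was called lower after quantile normalization, and all 3 calls ended after median-of-ratios scaling.

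Limma called 3367 rows, 1216 higher and 2151 lower in CD49f-high than in CD49f-low, and 6284 had an unadjusted p under 0.05. The replicate block raised the count to 5309, and leaving out CD49f-low replicate 3 gave 2201. The median log2 fold change of all rows was -0.15, and after median-of-ratios scaling the calls were 1614 higher and 1331 lower, after quantile normalization 1577 higher and 1431 lower. Camera called 24 of 34 lists, 16 up and 8 down, and with an estimated correlation 0 lists reached an adjusted p under 0.05, although 11 had an unadjusted p under 0.05. The fibroblast list (5 of 19 measured members fell, 6 adjusted over the list alone) and the fibrillar collagen list (1 of 27 measured members rose and 10 fell, 1 and 10 adjusted over the list alone) were not called (camera adjusted p = 0.229 and 0.133), but the former was with no filter (adjusted p = 0.0250) and by fry (0.0254), and the latter with no filter (adjusted p = 0.00271), after quantile normalization (0.0362), by fry (0.0183), without CD49f-high replicate 2 (0.0364) and without CD49f-high replicate 3 (0.0452).

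**Figure D3:**
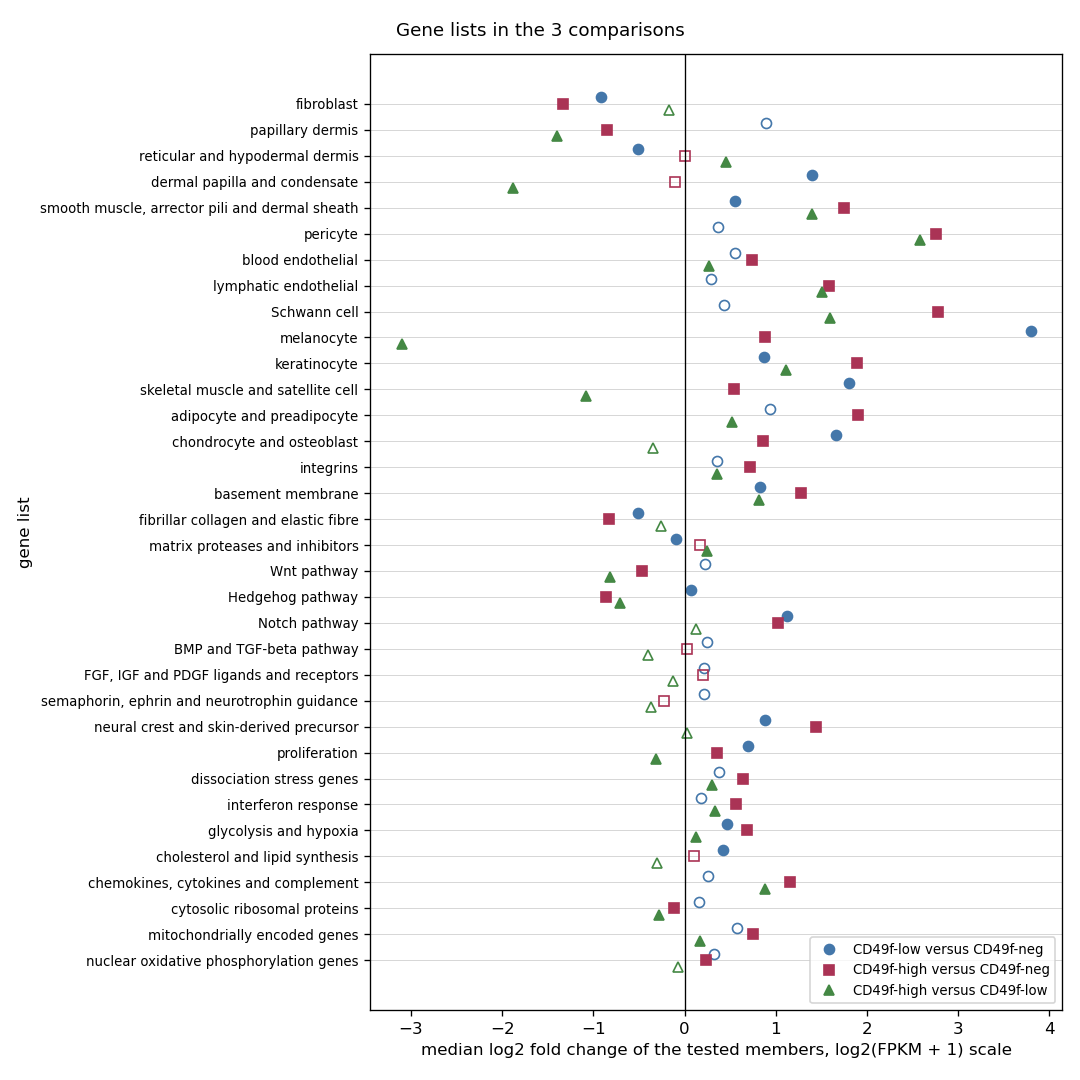
Median log2 fold change (x axis, log2(FPKM + 1) scale) of the measured members of 34 gene lists (y axis) in the 3 comparisons. Filled marks were called by camera with the preset correlation and open marks were not, with 17, 27 and 24 called. The medians of all rows were 0.21, 0.07 and -0.15.

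A joint test over the 3 gates asked which genes differed anywhere. It called 5856 rows, or 8995 with the replicate block. The low gate had the highest mean in 2545 of the 5856, lay between the other gates in 2978 and had the lowest mean in 333. After median-of-ratios scaling these were 1143, 2981 and 965 of 5089, and after quantile normalization 1201, 2690 and 1096 of 4987, a tally added after the results were seen. Acta2 was graded, at 1.27 ± 0.252, 37.5 ± 14.4 and 167 ± 77.2 FPKM from negative to high, as was the integrin gene Itga7 at 0.464 ± 0.154, 3.74 ± 1.01 and 39.8 ± 10.1. The Wnt modulator Sfrp2 was graded downwards, at 173 ± 17.5, 32.9 ± 3.64 and 9.71 ± 4.37. The Notch ligand Dll1 peaked in the low gate, at 0.527 ± 0.127, 12.4 ± 1.72 and 1.52 ± 0.613. In both steps, from negative to low and from low to high, 214 rows rose and 104 fell, 318 in all, and 863 were called in opposite directions. After median-of-ratios scaling 144 rose and 136 fell, and after quantile normalization 110 and 122, with 565 and 534 in opposite directions. The CD49f-low libraries enter both steps with opposite sign. Simulated groups with no difference gave 0 graded rows on average in 20 simulations. Such groups have almost no calls in either step after adjustment, so this outcome was fixed in advance and is no baseline for the 318. Independent lists of these sizes would share 155 rising and 56.3 falling rows, a figure that ignores the shared libraries. The noise of those libraries favours calls in opposite directions, and part of the 863 can come from it. The blocked fit gave 638 graded rows. Leaving out CD49f-neg replicate 2 gave 207, CD49f-neg replicate 3 gave 177, CD49f-low replicate 1 gave 205, CD49f-low replicate 2 gave 153 and CD49f-low replicate 3 gave 145.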

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

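None of the alternatives in this part was chosen after the results were seen. Itga6 kept its direction and its call in every alternative run, with log2 fold changes of 1.89 to 3.34 (CD49f-low versus CD49f-neg), 3.65 to 5.16 (CD49f-high versus CD49f-neg) and 1.53 to 1.83 (CD49f-high versus CD49f-low) and limma adjusted p from 3.09e-06 to 0.00219. Of 392 other fold changes of named genes, 367 kept direction and side of the threshold after median-of-ratios scaling, 370 after quantile normalization, 357 with no filter, 390 with no trend, 388 with a pseudocount of 0.1, 358 to 377 with 1 library left out, and 303 of the 303 still measured with the stricter filter. The 1 that reversed was Itgb1 between CD49f-low and CD49f-neg, at -0.0799 after median-of-ratios scaling and 0.20 before it. It had no call in either case, and the scaling takes out the shift of all rows, 0.21. Apart from Itgb1 and Itgb4, the 392 were named because they were called in these data, so most were bound to hold. Of all 3160 calls for low versus negative, 1654 were also called after median-of-ratios scaling and 1572 after quantile normalization. For high versus negative these were 4175 and 3871 of 4541, and for high versus low 2547 and 2637 of 3367. The replicate block gave 8995 calls over the 3 gates, 5806 for low versus negative, 5309 for high versus low and 638 graded genes, against 5856, 3160, 3367 and 318. It ended the call of Acta1 (high versus negative, 0.62 log2 units, adjusted p = 0.0431, or 0.0515 with the block), made that of Itgb1 (high versus low, adjusted p = 0.0262), ended 4 list calls in low versus negative (basement membrane, smooth muscle, Hedgehog and glycolysis) and that of the lymphatic list in high versus negative, and changed no other call of a named gene or list. The call of Acta1 also ended with no filter (0.101), after quantile normalization (0.0801) and without CD49f-neg replicate 1 (0.113) or 3 (0.109), CD49f-low replicate 1 (0.0579), 2 (0.0620) or 3 (0.0541) and CD49f-high replicate 1 (0.127) or 2 (0.0862). The stricter filter, which tests fewer rows, gave 2340 calls over the 3 gates, 1358, 1911 and 1323 in the 3 contrasts in the order above, 206 graded genes and 11 lists for low versus negative (17 in the report). With no filter 171 genes were graded, and the cause was not tested. Quantile normalization gave 2044 calls for low versus negative, 1040 higher and 1004 lower, against 2623 and 537 before it. It took out the shift of all rows, with a median of 0.21 before and -0.0119 after. Median-of-ratios scaling, which also takes it out, gave 2210 calls. Whether anything else lowered the count was not tested. A fold of at least 2, which removes smaller changes, left 2487 calls over the 3 gates, 938, 1853 and 1266 in the contrasts and 78 graded genes. With an estimated correlation camera called 1 list for low versus negative and 0 lists for each of the other contrasts (8, 8 and 11 at an unadjusted p under 0.05), whereas fry, which tests a list against no change and not against other genes, called 22 (19 up and 3 down), 25 (20 and 5) and 24 (11 and 13, against 16 and 8 by camera). Of the lists called by camera, fry called 15 of 17, 24 of 27 and 18 of 24, each in the same direction, and it called 7, 1 and 6 others. With 1 library left out, low versus negative had 1614 (without CD49f-neg replicate 3) to 3764 calls (without CD49f-high replicate 1), with 1726 and 1681 without CD49f-low replicates 2 and 3. High versus negative had 3232 to 4653, high versus low 2201 (without CD49f-low replicate 3) to 3585, and 145 (without CD49f-low replicate 3) to 395 genes were graded, with 207, 177, 205 and 153 without CD49f-neg replicates 2 and 3 and CD49f-low replicates 1 and 2. At the estimated depth 1 FPKM over 1 kilobase stands for 23.7 to 27.3 fragments, so genes near the filter rest on few fragments.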

Other observations

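The genes in the first paragraphs, the tests of explanations and the counts over other splits were chosen after the results were seen. So was the order of the gates after scaling, given with the joint test. The other counts and list calls with single libraries left out or after scaling were planned for the main results. Some Hox genes, which encode positional transcription factors, were lower in CD49f-high, and the group was not tested as a list. Of 19 rows that hold Hox genes, 9 were lower in CD49f-high than in CD49f-neg by limma (12 after either scaling), and 11 were lower in CD49f-high than in CD49f-low (7 after either scaling). Between CD49f-low and CD49f-neg, 2 were higher and 1 lower, but after either scaling 3 were lower. Hoxc8 stood at 8.99 ± 1.72, 7.38 ± 1.13 and 3.30 ± 0.642 FPKM in CD49f-neg, CD49f-low and CD49f-high, Hoxb9 at 7.32 ± 0.213, 4.10 ± 1.07 and 2.54 ± 0.910, and Hoxa9 at 2.47 ± 0.232, 3.51 ± 0.931 and 1.03 ± 0.334. In log2 units Hoxc8 changed by -1.21 from negative to high (limma adjusted p = 0.000804), Hoxb9 by -1.27 (adjusted p = 0.00180) and Hoxa9 by -0.79 (adjusted p = 0.0102).

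Beyond the pigment and dermal papilla lists, several genes were highest in CD49f-low. Mean FPKM in CD49f-neg, CD49f-low and CD49f-high were 42.0, 177 and 22.4 for Cd24a, a surface glycoprotein, and 10.2, 39.1 and 7.09 for the chemokine receptor Cxcr4. They were 2.04, 32.3 and 4.67 for Alx4 and 0.675, 14.4 and 1.34 for Tfap2c, both transcription factors, and 3.21, 11.5 and 1.10 for Runx3, another. They were 3.62, 23.6 and 6.14 for Gdf10, a BMP family member. All 6 passed limma's test in both steps. The adjusted p of Cd24a was 0.000401 from negative to low and 5.63e-05 from low to high. The alternatives were not run for these genes one by one.

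CD49f-high replicate 1 had lower Schwann cell genes and higher adipocyte genes than replicates 2 and 3, with medians of -1.76 and 1.76 log2 units against the others, and Adipoq at 132 FPKM against 2.30 and 1.16. After quantile normalization, which evens out differences in depth or scale, the medians were -1.80 and 1.64, further out than in replicates 2 and 3 (0.63 and 1.13, and -0.63 and -1.10), which argues against such a difference as the cause. No change of that size was seen in CD49f-low replicate 1, with medians of -0.13 for the Schwann list and -0.0222 for the adipocyte list. Those in CD49f-neg replicate 1 against the other CD49f-neg libraries were small too, at -0.00927 and 0.139. A smaller change shared by the libraries numbered 1 cannot be told apart from none by these medians. Whether CD49f-high replicate 1 held fewer Schwann cells stays open, as nothing apart from the Schwann genes themselves was tested. Fewer Schwann cells would not account for the adipocyte genes. Without this library limma called 3764, 4004 and 3281 genes in the 3 contrasts, and the adipocyte, glycolysis and mitochondrially encoded lists lost their calls in high versus low (camera adjusted p = 0.924, 0.136 and 0.806), as did the mitochondrial and nuclear oxidative phosphorylation lists in high versus negative (0.0678 and 0.471). In low versus negative the Schwann, adipocyte, mitochondrially encoded and nuclear oxidative phosphorylation lists gained a call, in direction up (0.0248, 0.000348, 0.0238 and 0.00140), and the Hedgehog list lost its own (0.0588). The nuclear list, not called in high versus low (0.299), was called there in direction down without this library (0.0373), but in direction up without replicate 2 (0.0175) or 3 (0.0291).

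Keratinocyte genes were higher in CD49f-high than in CD49f-neg, with 15 of 16 measured members called higher. The scale of the FPKM is argued against as the whole cause, since the median of all rows was 0.07 log2 units and that of the list 1.89. After median-of-ratios scaling 15 were still called higher, which adds little, as so small a shift could hardly end these calls. Basal keratinocytes carry CD49f, while the labels' gate is for mesenchymal cells, so epidermal cells carried through the sort were weighed. Their genes would go up and down together among the CD49f-high libraries, and 13 of 16 members were lowest in replicate 3 (median -0.75 against the others, 0.45 in replicate 2). As 13 of 15 pericyte members were lowest in replicate 2 and 19 of 21 Schwann members in replicate 1, this is no mark of keratinocytes, and carried-over cells cannot be told apart from other causes by it. The most abundant members in CD49f-high were Dst at 14.5 FPKM (6.75 in CD49f-neg), the row that holds Krt5 at 8.97 and Itgb4 at 8.38, of which Itgb4 also stands in the integrin list, and the members Cdh1 and Cdh3 were higher in CD49f-low (18.7 and 10.3 FPKM) than in CD49f-high (3.54 and 1.57). Keratinocyte genes expressed by the sorted cells themselves stay open, as no test here separated the explanations.

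The median log2 fold change of all rows was 0.21 for low versus negative and -0.15 for high versus low. In CD49f-neg the 100 most abundant rows held 31.0% of the estimated fragments, against 21.3% in CD49f-low and 21.1% in CD49f-high, and the transcripts of Col1a1, Col1a2 and Col3a1 held 11.2% to 13.7%, 4.43% to 5.47% and 3.26% to 4.89%. A smaller share for these transcripts leaves more for all others, and the shift computed from the shares was 0.19 for low versus negative, so this may account for that shift. The computed shift for high versus low was 0.00252, which argues against the share of these 100 rows as the cause there. The rows left out were not covered, so a change in their share stays open. For high versus negative the computed shift was 0.19 beside an observed 0.07. What moved the median down in CD49f-high stays open, as the tests did not reach it.

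Other splits of the same libraries into groups of the same sizes were fitted. For low versus negative the real split called 3160 genes and the highest of the others 0 by limma, for high versus negative 4541 and 1, and for high versus low 3367 and 3. Of lists the real splits called 17, 27 and 24 and the highest others 13, 15 and 20, so other splits came much nearer to the real list counts than to the real gene counts, least so for high versus negative. In each of these tests 1 of 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. The real splits part all 3 replicate numbers between the groups. Among the others that do so, the highest counts were 0, 1 and 0 genes and 11, 15 and 20 lists, and among those that part fewer 0, 1 and 3 genes and 13, 13 and 17 lists. In the test over the 3 gates 1 of 100 splits drawn reached the real 5856 genes and the highest other gave 1744. Of all 36 splits that part all numbers 1, the real one, reached it and the highest other gave 1569. That share is under 0.05, and the lowest that these splits could give. It argues against chance for this count without excluding it, since groups that mix gates have a wider spread, which can lower their counts. The 5 other splits that kept the CD49f-high libraries together gave 1271 to 1744 and the rest at most 763, which points to those libraries as the main structure of the samples. Of graded genes 1 of 100 splits, the real one, reached 318 and the highest other gave 0 by limma. The other splits mix gates within their groups, which can widen the spread enough to hold such counts at 0, so this comparison decides nothing about chance.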
